A study of Homo sapiens with 4 samples.

How the data were processed

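RNA from HEK293 cells, a human embryonic kidney line that grows as an adherent layer, was hybridised to 4 Affymetrix expression arrays. Per the labels' protocols, cells grown with serum were kept overnight without it and then given lysophosphatidic acid (LPA, a serum phospholipid that acts on G protein-coupled receptors) at 1 µM for 2 h. The labels name 2 untreated arrays and 2 LPA arrays, with replicate numbers 1 and 2 in each group. They do not state that the replicates came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. The titles of the untreated arrays carry the letters Vc, which the labels do not explain and which can stand for a vehicle or vector control, while their treatment is given as none. The labels also do not state what these cells received in place of LPA, nor whether a replicate number marks a shared day.

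The deposited values are intensity values on a linear scale, 1 per probe set and array, made with MAS5 per the submitters' processing notes. The version, the background settings and the target of the scaling are not given in the sources used here, and no detection calls were used. The labelling is described by a manual for whole-transcript labelling, while the probe sets are those of an array for 3′ ends, so whether RNA without a poly(A) tail was labelled is not known. The mean of each array after trimming the lowest and highest 2% of probe sets was 500.1 on all 4 arrays, so the intensities had been scaled array by array before deposit. No further normalization was applied in the primary analysis. Such scaling sets a common level but does not equalise the shape of the intensity distribution between arrays.

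Of 54675 probe sets, the annotation gave 1 gene symbol to 41097, several to 1801 and none to 11777. Symbols were looked up through the Entrez gene identifier for 41043 probe sets, and 0 differed from the current reference. Only probe sets with 1 symbol were named, so genes whose probe sets list several symbols were not analysed here. Each of 19775 genes was represented by its brightest probe set over all 4 arrays, and genes below the 40th percentile of mean log2 intensity (a signal of 70.5) were left out, which kept 11865 genes.

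Values were taken as log2(intensity + 1), so a fold is on that scale and understates the difference of dim genes. The 2 groups were compared with limma (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. The replicate number was not a term in this model. Gene lists were compared with camera, from the same package, with an inter-gene correlation preset to 0.01 and adjustment over the 24 lists, each with at least 5 tested members. The standard error (SE) given beside a log2 difference is limma's moderated value, and a standard deviation (SD) is over the 2 arrays of a group. The number of arrays limits the precision: the median SE of a log2 difference was 0.244.

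The 24 lists, the comparison, the test, the rule for named genes and most alternatives were chosen before the data were examined. The rule named up to 12 genes with the largest positive and 8 with the largest negative difference among those past the threshold with no overlap between groups. With fewer than 5 in a direction, it was filled to 5 with the genes of smallest unadjusted p and at least a 1.5-fold difference. It added members of each list by smallest p, up to 4, of which fewer are given for lists that did not pass, and CCN1, CCN2, ANKRD1, FOS, EGR1, SRF, LPAR1 and LPAR2 whatever their test. The lists covered immediate early transcription factors, MAP kinase feedback regulators, SRF and MRTF targets, YAP and TAZ targets, NF-kappaB targets, CREB targets, growth factors and pericellular proteolysis, TGF-beta and BMP targets, and LPA receptors with LPA metabolism. The others were FOXO and starvation targets, the integrated stress, unfolded protein, heat shock, interferon and hypoxia responses, cholesterol synthesis, p53 targets, S phase and mitosis, ribosome biogenesis, oxidative phosphorylation, genes of the HEK293 background, markers of other cell types, and reference genes. A further list, which did not pass, is not described here, though it counts among the 24 in the adjustment.

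The gene test was tested on simulated data with the 11865 genes of this comparison, 200 of them changed. It recovered 26% of 100 genes changed 2-fold, 78% of 50 changed 4-fold and 94% of 50 changed 8-fold, and called 3 unchanged genes. The list test found a list of 15 genes shifted by 0.5 on the log2 scale in 50 of 50 draws with the preset correlation and in 0 of 50 with an estimated one, and called 0.17% of unshifted lists. These simulated arrays had independent errors, with no array differing from the rest across many genes. In the real comparison 207 genes had an unadjusted limma p under 0.05, where chance gives 593. The recovery rates can therefore overstate what the test could find here.

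Alternatives were other pseudocounts (16 and 64), quantile normalization, median centring, cyclic loess, no filter or one at the 60th percentile, the mean of a gene's probe sets, every probe set on its own, eBayes without the trend or with a robust prior, the replicate number as a block, an estimated inter-gene correlation, fry in place of camera (a test against no change and not against other genes), and leaving out each array in turn. In the last, the lone array of a group was assumed to vary like the other group. No chromosome positions were used. Computations used R 4.3.3 with limma 3.58.1 and the data.table package at 1.17.8, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.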

Results

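Gene expression was measured in HEK293 cells 2 h after 1 µM LPA and in untreated cells, with 2 arrays per group. Array medians were 70.3 and 76.1 for untreated replicates 1 and 2, and 70.7 and 72.3 for LPA replicates 1 and 2. LPA replicate 2 had the lowest maximum intensity, 62508, against 93776 to 104012 on the other arrays. Its ACTB probe sets also had the highest 3′-to-5′ intensity ratio, 18.8 against 12.6 to 13.6, a measure that depends on RNA integrity and on the labelling, which is uncertain here. The same ratio for GAPDH set it less apart, at 1.38 against 1.35 on LPA replicate 1 and 1.25 and 1.22 on untreated replicates 1 and 2. No pair of arrays shared more than 1 identical value over all probe sets. Across genes, which are not independent replicates, arrays of the same replicate number correlated most closely (r = 0.983 for number 1 and 0.981 for number 2). The 2 untreated arrays had r = 0.971 and the 2 LPA arrays r = 0.979.

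The comparison of LPA with no treatment asks which transcripts differ after 2 h of LPA in serum-starved cells. The probe set for RNA45SN5, the precursor transcript of ribosomal RNA, read 296 and 215 in untreated cells and 1380.2 and 3659 after LPA, a log2 difference of 3.15 ± 0.41 (SE, 2 arrays per group). A second RNA45SN5 probe set read 308 and 417 against 835 and 1863. FOSB, a subunit of the AP-1 transcription factor, read 30.0 and 72.4 against 185 and 259, a log2 difference of 2.21 ± 0.52. Among genes with lower values after LPA, CGAS, the sensor of cytosolic DNA, differed by -1.88 ± 0.38, and CS, the citrate synthase of the citric acid cycle, by -0.72 ± 0.16. None of these passed the threshold over all genes in this comparison: limma gave adjusted p = 0.508 for RNA45SN5 and 0.9999 for the others. As an alternative, limma with the replicate number as a block gave adjusted p = 3.78e-10 for RNA45SN5, 0.0153 for CS, 0.0338 for FOSB and 0.0383 for CGAS. Adding quantile normalization to the block made these 0.000454, 0.00992, 0.182 and 0.136.

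In all, 0 of 11865 genes passed. An unadjusted limma p under 0.05 was found for 207, 140 of them higher and 67 lower after LPA, against 593 that chance gives. Taking the replicate number as a block gave 32 genes past the threshold and 1014 with an unadjusted limma p under 0.05. The labels do not state what the number marks. The low count without the block does not show that LPA had no effect. Both LPA values lay above both untreated values for 1712 genes (14.4%) and below them for 1488 (12.5%), where chance gives 16.7% in each direction. The other genes that the fixed rule named as higher were ZNF564, a zinc finger protein (54.6 and 16.9 against 220 and 235, log2 difference 2.86 ± 0.59), ACCS (59.4 and 17.2 against 208 and 161, 2.47 ± 0.62) and ITFG1 (1.19 ± 0.26). Those named as lower were the long non-coding RNA LINC01210 (-1.83 ± 0.42), the metallothionein-like MT1HL1 (916 and 1174 against 567 and 474) and ATP6V0E1, a subunit of the vacuolar proton pump (-0.75 ± 0.15). For ITFG1 and ATP6V0E1 other probe sets of the gene disagreed, with log2 differences of -0.33 for the next brightest of ITFG1 and 0.25 for that of ATP6V0E1. Untreated values of ZNF564 and ACCS, 1 of those of FOSB, and the LPA values of CGAS and LINC01210 lay below the filter's signal of 70.5 and are not shown to be above background: with a pseudocount of 64 the log2 differences were 1.57, 1.31, 1.33, -1.28 and -1.17. Leaving out 1 array gave 2 genes without untreated replicate 1, 3 without untreated replicate 2, 1 without LPA replicate 1 and 0 without LPA replicate 2. RNA45SN5 was among the genes called in each of the first 3 cases.

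**Figure D1:**
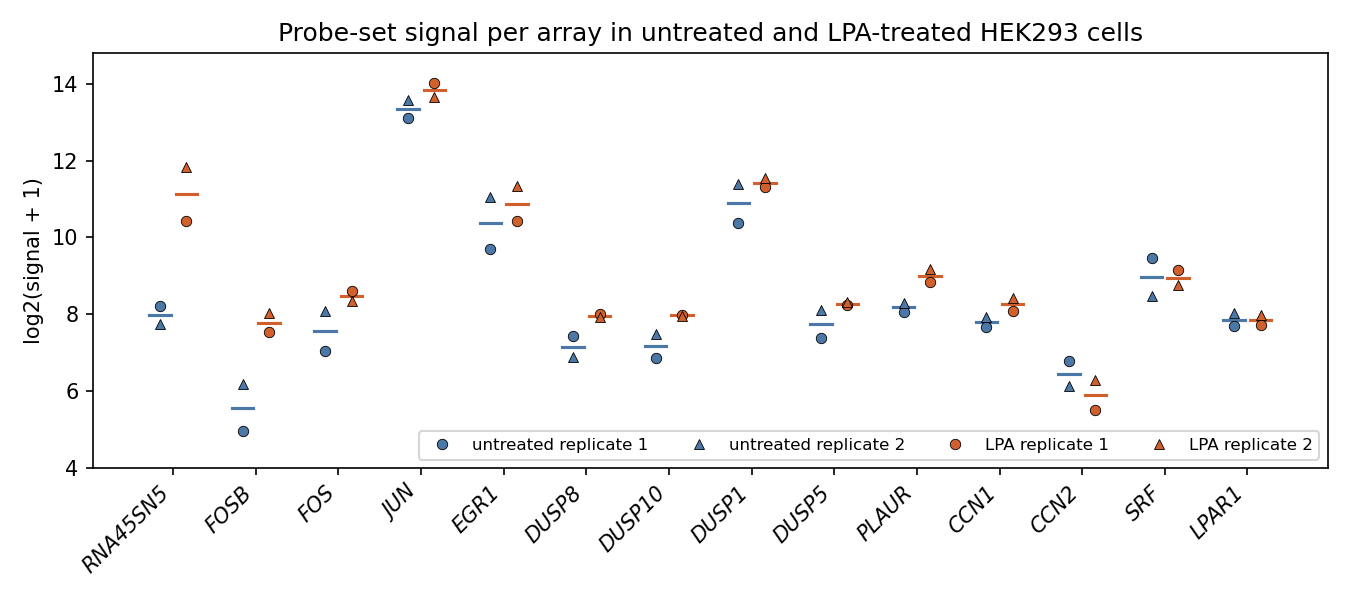
Log2(signal + 1) of 14 named genes on each array; the x axis lists the genes, colours separate untreated from LPA, symbols mark replicates 1 and 2, and bars are group means. RNA45SN5 and FOSB are separated by 3.15 and 2.21 on the log2 scale, and none of the genes passed the threshold in the primary analysis.

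Immediate early transcription factors, which growth factors and serum induce within minutes to hours, rose as a set after LPA. Of 23 tested members 17 had a positive mean difference and 6 had both LPA values above both untreated values. FOSB had the largest difference and FOS, another AP-1 subunit, the next (131 and 271 against 389 and 323, log2 difference 0.90 ± 0.39). The AP-1 subunits JUN (0.49 ± 0.20) and JUND (0.29 ± 0.15) and the zinc finger factor KLF10 (0.34) also had no overlap between groups at their brightest probe sets. The other 3 JUN probe sets above the filter overlapped (0.42, 0.457 and 0.345, each lower after LPA in replicate number 2). MAFF (0.52) and the nuclear receptor NR4A2 (0.51) overlapped too, and EGR4 was lower on both LPA arrays (-0.42). EGR1, a zinc finger factor, read 837 and 2127 against 1366 and 2594 (0.50 ± 0.43), so the untreated arrays differed by more than the groups did. The list's mean log2 difference was 0.24, its median 0.14, and camera gave adjusted p = 0.0362, with 0 members past the threshold over all genes and 0 adjusted over the list alone. The camera adjusted p was 0.878 with an estimated correlation. That version found a simulated shift of 0.5 in 0 of 50 draws, so its p decides nothing here or for the other lists. Within replicate numbers the list's median difference was 0.31 for number 1, at percentile 100 of 10000 lists matched on brightness, and 0.15 for number 2, at percentile 93.2 and inside their central 95% (-0.129 to 0.192), so only number 1 stood apart from equally bright genes. Each such percentile compares 1 array with 1 array. Between the 2 untreated arrays most lists lay inside the central 95%, but the hypoxia and integrated stress lists lay at percentile 100 and ribosome biogenesis at 0.19. A high percentile therefore does not separate LPA from other differences between arrays. The call was lost without untreated replicate 1 (mean 0.13, adjusted p = 0.556), without LPA replicate 1 (0.32, 0.056) and without LPA replicate 2 (0.16, 0.173), and under quantile normalization (0.22, 0.0749), cyclic loess (0.22, 0.0603) and median centring (0.27, 0.0546). It was also lost with the mean of all probe sets (adjusted p = 0.4), without the intensity trend (0.234) and with fry (0.999), which tests a list against no change and not against other genes, within a range of 0.00191 to 0.999 over all alternatives.

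Feedback regulators of MAP kinase signalling, a list of inhibitors the pathway induces together with some of its other target genes, such as the cyclin CCND1, also rose as a set. Of 15 tested members 12 had a positive mean difference and 6 had no overlap between groups. Among the dual-specificity phosphatases, which remove phosphate from MAP kinases, DUSP8 read 172 and 117 against 255 and 243 (0.81 ± 0.35) and DUSP10 115 and 179 against 253 and 248 (0.80 ± 0.36). DUSP1, whose groups overlapped, differed by 0.53 ± 0.29 (0.031 to 1.04 over the alternatives) and DUSP5 by 0.52 ± 0.34 (0.16 to 0.88). DUSP4 differed by 0.079 and DUSP7 by -0.15. SPRED3, an inhibitor of RAS signalling, differed by 0.67 with no overlap. The list's mean was 0.29 and its median 0.24, with camera adjusted p = 0.0362, 0 members past the threshold over all genes and 0 adjusted over the list alone. With an estimated correlation, 0.025 for this list, the camera adjusted p was 0.878, which again cannot decide. Medians were 0.22 in replicate number 1, at percentile 98.9 of lists matched on brightness, and 0.20 in number 2, at percentile 86.7 and inside their central 95% (-0.133 to 0.308). As above, a high percentile between 2 arrays does not separate LPA from other differences between them. The call was lost without untreated replicate 1 (mean 0.20, adjusted p = 0.444) and without LPA replicate 2 (0.21, 0.248), under quantile normalization (0.25, 0.119), cyclic loess (0.25, 0.127), median centring (0.33, 0.0546) and a filter at the 60th percentile (0.14, 0.659). It was also lost with the mean of all probe sets (adjusted p = 0.284) and with fry (0.999), within a range of 0.0161 to 0.999.

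Targets of SRF and its coactivator MRTF, which encode actin cytoskeleton proteins, did not pass as a set (19 tested, mean log2 difference 0.11, camera adjusted p = 0.564). The tropomyosin TPM2 read 101 and 33.2 against 133 and 156 (1.29 ± 0.57, from 0.50 to 2.08 over the alternatives, with 1 untreated value below the filter's signal), and differences were smaller for others: caldesmon (CALD1) 0.18 ± 0.15, FHL2 0.20 ± 0.20, smooth muscle actin (ACTA2) 0.30 ± 0.32 and SRF itself -0.017 ± 0.35. Other TPM2 probe sets lay below the filter, and other CALD1 probe sets above it ranged from -0.11 to 0.39. Targets of the Hippo pathway effectors YAP and TAZ did not pass either (17 tested, mean 0.045, adjusted p = 0.624). Within that list both LPA values were above both untreated values for CCN1, a secreted matrix protein (204 and 245 against 271 and 344, 0.45 ± 0.31), AMOTL2 (0.37 ± 0.25), PTPN14 (0.31 ± 0.20), CCDC80 (0.47) and AJUBA (0.17), and below them for DLC1 (-0.23) and TGFB2 (-0.28). ASAP1 differed by 0.28 ± 0.22, and CCN2, the relative of CCN1, read 109 and 68.8 against 44.9 and 77.7 (-0.54 ± 0.52). ANKRD1 read 35.8 and 1.49 against 4.40 and 28.7, below the filter, and was not tested. For these lists 0 members passed over all genes and 0 adjusted over the list alone.

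Growth factors and pericellular proteolysis genes gave a mean of 0.085 and a median of -0.081 over 11 tested members, with camera direction upward and adjusted p = 0.624. In that list PLAUR, the urokinase receptor, read 267 and 315 against 459 and 575 (0.82 ± 0.27), with 0.78 in replicate number 1 and 0.86 in number 2. Its other probe sets above the filter gave 0.57 and 0.38 but were less even. The first fell from 270.6 to 188.8 in number 2, and the second from 173.4 to 122.8 in number 1. LPA receptors, the G proteins they use and enzymes of LPA metabolism had a mean of 0.036 over 13 tested genes (adjusted p = 0.856). The receptor LPAR1 read 205 and 259 in untreated cells and 211 and 252 after LPA, a difference of 0.0010 ± 0.32, and turned to -0.068 under quantile normalization. Its other probe sets above the filter gave -0.2 and, with 85 and 122.8 against 161.8 and 147, 0.589. LPAR2 read 77.7 and 83.7 against 51.2 and 84.7 (-0.29 ± 0.48), close to the filter, and its other probe set gave 1.82. PLPP3 and PLPP1, phosphatases that degrade extracellular LPA, differed by 0.52 ± 0.24 and 0.33 ± 0.23, but their next brightest probe sets by -0.016 and -0.165.

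Genes of oxidative phosphorylation fell as a set, with 13 of 15 tested members below 0 and 4 with no overlap between groups. COX5A, a subunit of cytochrome c oxidase, differed by -0.22 ± 0.16 (its other probe set by 0.54), and ATP5F1A, a subunit of the mitochondrial ATP synthase, by -0.24 ± 0.18. The list's mean was -0.11 and its median -0.11 (camera adjusted p = 0.0362), with 0 members past the threshold over all genes and 0 adjusted over the list alone. The camera adjusted p was 0.878 with an estimated correlation, which again cannot decide. That correlation was 0.477 for this list, far above the preset 0.01, and the preset p is too small if the members vary together that closely. The difference was present in 1 replicate number: the median was 0.0090 in number 1 and -0.23 in number 2, whose LPA array had the low maximum intensity and the high ACTB 3′-to-5′ ratio. Quantile normalization gave a mean of 0.000 (adjusted p = 0.99) and cyclic loess 0.004 (0.994), within a range of 4.45e-05 to 0.999 over all alternatives, and the call was also lost without untreated replicate 1 (-0.14, 0.19), without untreated replicate 2 (-0.072, 0.476) and without LPA replicate 2 (-0.030, 0.685). Median centring (adjusted p = 0.0837), no filter (0.231), a filter at the 60th percentile (0.075), the mean of all probe sets (0.54), no intensity trend (0.234) and fry (0.999) ended it too. Other sets of abundant transcripts also had negative means: ribosome biogenesis genes averaged -0.13 (adjusted p = 0.0671), with 0.017 and -0.24 as the medians of the 2 numbers, and reference genes -0.095 (0.329), with 0.028 and -0.15. Under quantile normalization the mean of the reference genes became 0.034. PPIA and GAPDH, both used as internal standards, differed by -0.35 ± 0.21 and -0.33 ± 0.22.

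**Figure D2:**
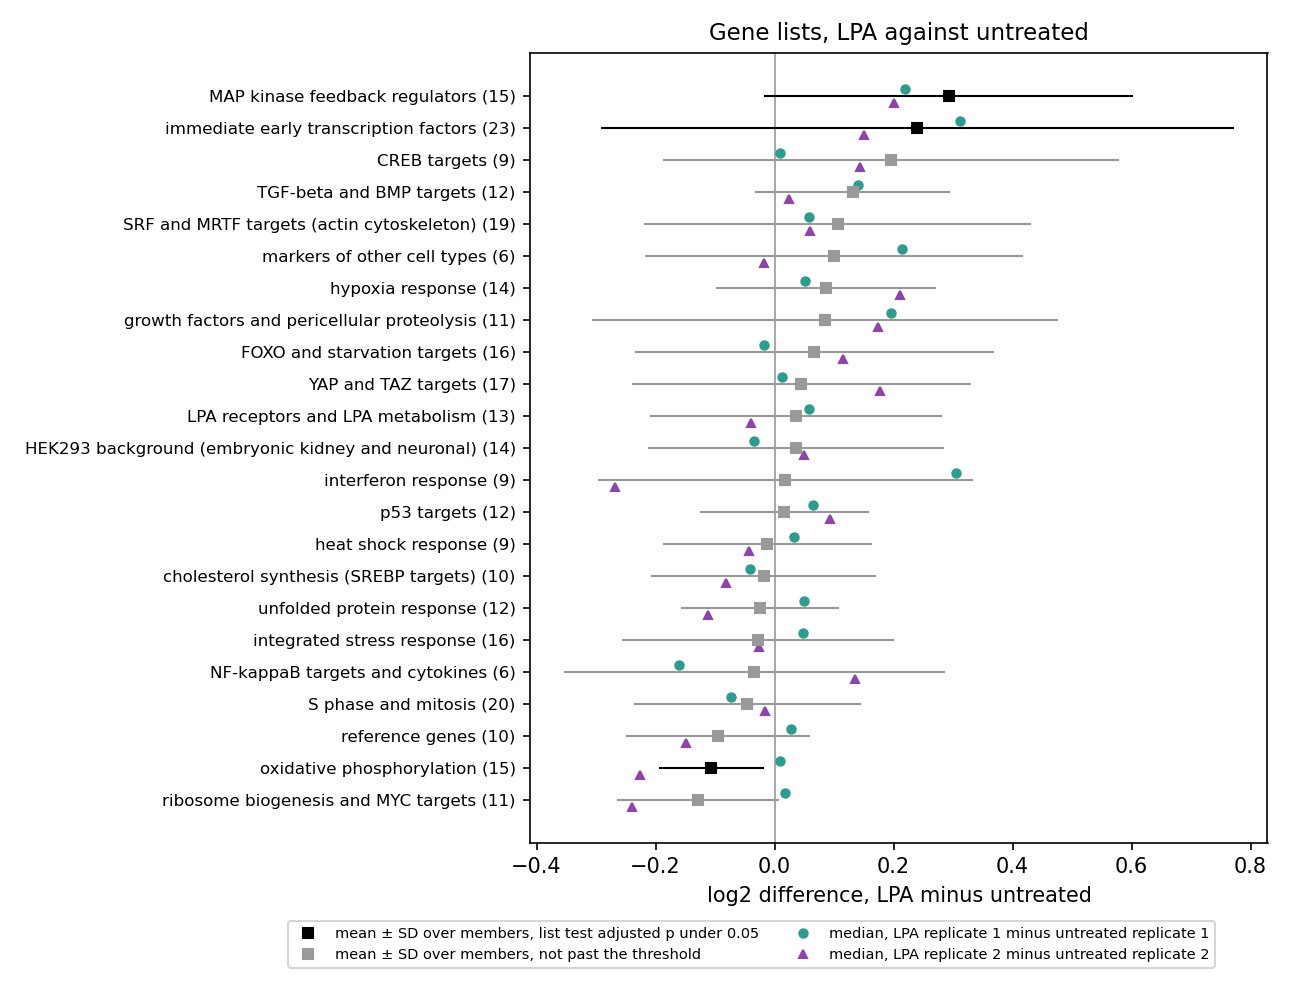
Log2 difference of LPA from untreated for each of 23 gene lists (number of tested genes in brackets); squares and lines are the mean and SD over members, black where the list test passed, and circles and triangles are the medians within replicate numbers 1 and 2. MAP kinase feedback regulators lie highest, with a mean of 0.29, and oxidative phosphorylation shows medians of 0.0090 and -0.23 in the 2 replicate numbers and a mean of 0.000 under quantile normalization.

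The 14 remaining lists did not pass, with camera adjusted p from 0.541 to 0.91. The largest mean was that of CREB targets (0.20), then TGF-beta and BMP targets (0.13), where the inhibitor SMAD7 differed by 0.43 ± 0.36. Markers of other cell types averaged 0.10 over 6 genes, with CDH1, the epithelial cadherin, at 0.47 ± 0.30. Hypoxia response genes averaged 0.087, with hexokinase HK2 at 0.35 ± 0.17. FOXO and starvation targets averaged 0.067, with CCNG2, a cyclin that restrains growth, at 0.53 ± 0.18 and KLHL24 at -0.60 ± 0.24. NF-kappaB targets averaged -0.034 over 6 genes, where the inhibitor NFKBIA differed by -0.63 ± 0.34. The integrated stress response averaged -0.028, with its transcription factor ATF4 at -0.38 ± 0.19, and the unfolded protein response -0.025, with the chaperone DNAJB9 at 0.29 ± 0.21. The heat shock response averaged -0.012 (BAG3 0.27 ± 0.19), cholesterol synthesis -0.018 (INSIG1 0.34 ± 0.18) and S phase and mitosis genes -0.046 (E2F1 -0.61 ± 0.31). The interferon response averaged 0.018 (IFIT1 0.48 ± 0.39), but the replicate numbers went opposite ways. Its median was 0.305 in number 1 and -0.268 in number 2, at percentiles 97.36 and 1.25 of lists matched on brightness. For p53 targets the mean was 0.016 and the median -0.018, and for genes of the HEK293 background 0.036 and -0.0020, with an upward camera direction in both; MDM2 differed by 0.27 ± 0.18 and vimentin (VIM) by -0.37 ± 0.17. Other probe sets above the filter differed in sign for KLHL24 (0.065, -0.13 and 0.30), E2F1 (0.26), HK2 (-0.43 and -0.56), CCNG2, MDM2 and VIM. In all 14 lists 0 members passed over all genes and 0 adjusted over the list alone.

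**Figure D3:**
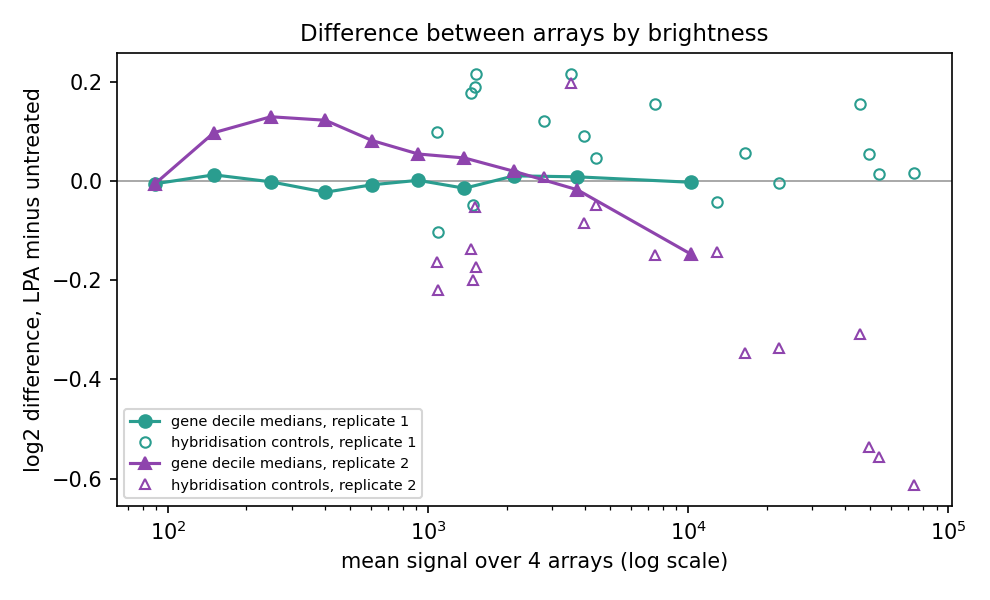
Log2 difference between the LPA and the untreated array of the same replicate number against mean signal (log axis); filled points are medians of genes in 10 equal groups by brightness, and open points are hybridisation controls. In number 1 the medians stay between -0.023 and 0.012, and in number 2 they run from 0.129 in the third group to -0.148 in the brightest.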

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

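The tests of mature ribosomal RNA, of array scaling, of the hybridisation and poly(A) controls and of the called genes per list were chosen after the results they bear on were seen. The brightness-matched lists and the list test between replicate numbers were chosen before their own outcomes were seen, but after the patterns they were meant to explain.

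A signal appeared among the probe sets that carry no single gene symbol and so lay outside the gene comparison. A probe set to which the array's annotation gives no gene symbol read 358 and 408 in untreated cells and 2739 and 2450 after LPA. Its log2 difference was 2.76 ± 0.22 (SE), higher in 2 of 2 LPA arrays, with limma adjusted p = 0.000197 over 8113 such probe sets, of which 289 had an unadjusted p under 0.05. It was looked at because it passed the threshold where no named gene did.

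Both probe sets of the ribosomal RNA precursor RNA45SN5 were brighter on both LPA arrays. Carry-over of mature ribosomal RNA into the labelling was examined with 5 control probe sets for the mature small- and large-subunit RNAs. Another, for the 3′ part of the large-subunit RNA, was left out as near background (43.5 and 18.1 in untreated cells, 14.7 and 43.5 after LPA). The median log2 difference of the 5 was 0.29 (from 0.028 to 0.756), below the 2.33 that the precursor's difference less 2 SE would need. The brightest, up to 40349 in untreated cells, had little room for such a rise below the arrays' maxima. The middle parts, from 4935 to 6741 in untreated cells, had room and differed by 0.289 and 0.17. These argue against carry-over as large as the precursor's difference, and a smaller one is not excluded. The choice of scaling mattered little, as 3 other scalings moved the difference by at most 0.047. The arrays already had equal trimmed means (500.1), so a large move was hardly possible and no conclusion on a cause is drawn. An effect of LPA on the precursor may account for the brighter probe sets and stays open, untested. Technical sources without a test here also stay open, such as the probes binding other RNA or the labelling method, which is uncertain. The precursor did not pass the threshold over all genes in the comparison itself.

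Abundant transcripts, those of oxidative phosphorylation among them, were dimmer after LPA in replicate number 2. A compressed bright end of LPA replicate 2 could account for this: 7 of 7 bright hybridisation control probe sets, for RNA added in equal amounts to each array, were dimmer there than on untreated replicate 2, with a median log2 difference of -0.35, against 0.016 in number 1. These probe sets measure only the transcripts bioD and cre, so they are not independent. The oxidative phosphorylation median of -0.23 lay at percentile 45.5 of 10000 lists matched on brightness (central 95%, -0.363 to -0.104), so the list did not stand apart from equally bright genes on these arrays. No value here sets these genes apart from others as bright, so an effect of LPA on them in particular is not shown, and a small one is not excluded.

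The arrays differed by replicate number more than by treatment: the same limma test between numbers called 445 genes, 197 higher and 248 lower in number 2 (81 and 283 under median centring), against 0 between treatments, which points to a structure of the samples. Separate preparation of the 2 numbers may contribute, since 22 of 23 poly(A) control probe sets, for RNA spiked in before labelling, were higher in number 2 (median log2 difference 0.32), while hybridisation controls differed by a median of 0.008. That median balances opposite differences and does not show equal hybridisation. The hybridisation controls were higher on untreated replicate 2 than on untreated replicate 1, and most were lower on LPA replicate 2 than on LPA replicate 1. The poly(A) probe sets measure only the transcripts dap, lys, phe and thr, so they are not independent. A difference between the cultures also stays open: 3 gene lists held more of the called genes than other genes did by Fisher's exact test, adjusted over the lists. That test counts genes as independent and does not measure the spread between cultures. The list test with an estimated correlation passed 0 lists between numbers, but it found a simulated shift of 0.5 in 0 of 50 draws, so it could not have decided this. Preparation and culture cannot be told apart where both follow the number.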

How the results depend on the processing

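Cyclic loess and the combinations with the replicate block were chosen after the data were seen, and the other alternatives before. RNA45SN5 and FOSB kept a positive difference under every alternative that gave them a value (2.45 to 3.85 and 1.33 to 2.83 on the log2 scale), and CGAS and CS a negative one. The count of 0 genes was kept under all scalings, pseudocounts, filters and variance models, while every probe set on its own gave 1, a probe set with no symbol.

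With the replicate number as a block, 32 genes passed, 19 higher and 13 lower, among them RNA45SN5, ITFG1, ATP6V0E1, FOSB, CGAS and MT1HL1, and 2 lists passed, the oxidative phosphorylation mean of -0.106 being the call lost (adjusted p = 0.199). The block together with quantile normalization gave 4 genes (2 higher, 2 lower), 2 lists (immediate early factors and, not past before, the hypoxia response at 0.103), a mean of 0.252 for MAP kinase feedback regulators, no longer past the threshold, and 0.000 for oxidative phosphorylation. The 4 genes were RNA45SN5, WDR82, ATP6V0E1 and CS. ITFG1, FOSB, CGAS and MT1HL1 lost the call at nearly unchanged differences, 2.19 for FOSB. With an estimated correlation the block gave 0 lists. Deviations of same-numbered arrays from their group means had a correlation over genes of 0.33, which with 2 pairs does not establish pairing. The cause of the changes below was not tested, except that fewer members or arrays enter under a stricter filter or with an array left out.

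The number of lists past the threshold, 3, became 0 under quantile normalization, median centring, the mean of all probe sets, an estimated correlation, fry and cyclic loess, and 1 with a filter at the 60th percentile or without the intensity trend. The test with an estimated correlation found a simulated shift of 0.5 in 0 of 50 draws, so calls lost under it do not count against a list. Fry was not simulated. Calls were lost for immediate early factors at means of 0.222 (quantile), 0.273 (median centring), 0.213 (mean of probe sets), 0.219 (cyclic loess) and an unmoved 0.240 (no trend, estimated correlation, fry). For MAP kinase feedback regulators they were lost at 0.252, 0.327, 0.370 and 0.248 in the same order, at 0.139 with the 60th percentile filter and at 0.293 with an estimated correlation and fry. For oxidative phosphorylation they were lost at -0.073 (median centring), -0.115 (mean of probe sets) and -0.106 (no filter, 60th percentile filter, no trend, estimated correlation, fry), and its sign turned at 0.000 (quantile) and 0.004 (cyclic loess).

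Among means and genes that did not pass in the primary analysis, the sign turned under quantile normalization for reference genes (0.034), the interferon response (-0.012), p53 targets (-0.0010), the heat shock response (0.085) and LPAR1 (-0.068), with equal values when the block was added. Under cyclic loess it turned for the same 5 (0.0090, -0.021, -0.0070, 0.064 and -0.058) and for cholesterol synthesis (0.0040). Under median centring it turned for SRF (0.016), cholesterol synthesis (0.015), the heat shock response (0.021), the unfolded protein response (0.0080) and the integrated stress response (0.0060). Without a filter it turned for markers of other cell types (-0.415), YAP and TAZ targets (-0.042) and 1 list not described here (-0.026). The mean of all probe sets turned the unfolded protein response (0.046), hypoxia (-0.142), interferon (-0.037), cholesterol synthesis (0.054), integrated stress (0.103), FOXO (-0.066), NF-kappaB (0.136) and SRF and MRTF lists (-0.039), and HK2 (-0.21), LPAR2 (0.77), SRF (0.20) and COX5A (0.16). A pseudocount of 16 turned LPAR2 to 1.29 and one of 64 to 0.73.

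Leaving out 1 array in turn gave 0 to 3 genes (0 to 3 higher, 0 to 0 lower) and 1 to 5 lists. Lists gained were hypoxia, ribosome biogenesis, reference genes and the integrated stress response, the last called in opposite directions: lower without untreated replicate 1 or LPA replicate 2 and higher without untreated replicate 2. Means ranged from 0.132 to 0.348 for immediate early factors, 0.195 to 0.392 for MAP kinase feedback regulators and -0.182 to -0.030 for oxidative phosphorylation. Ranges that crossed 0 were -0.084 to 0.218 for FOXO targets, -0.045 to 0.117 for the HEK293 background, -0.032 to 0.105 for LPA receptors and metabolism, -0.145 to 0.077 for NF-kappaB targets, -0.114 to 0.023 for S phase and mitosis, -0.082 to 0.173 for YAP and TAZ targets, -0.153 to 0.117 for cholesterol synthesis, and -0.104 to 0.274 for growth factors. They were -0.091 to 0.066 for heat shock, -0.252 to 0.426 for hypoxia, -0.344 to 0.289 for integrated stress, -0.142 to 0.179 for interferon, -0.118 to 0.318 for markers of other cell types, -0.059 to 0.091 for p53 targets, -0.300 to 0.044 for ribosome biogenesis and -0.066 to 0.015 for the unfolded protein response. Among genes they were -0.051 to 0.66 for ACTA2, -0.18 to 1.17 for EGR1, -0.0087 to 0.96 for IFIT1, -0.17 to 0.17 for LPAR1, -0.65 to 0.070 for LPAR2 and -0.52 to 0.49 for SRF.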

Other observations

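The comparison between replicate numbers was chosen after the arrays were seen to group by number, as was Fisher's test below. The test of the starting level of immediate early genes was chosen before its result was seen. Fisher's test counts genes as independent, though genes of a list can vary together on the same arrays. Its p-values therefore do not measure the spread between arrays or cultures.

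Part of the integrated stress response, which cells switch on when amino acids or protein folding fail, was higher in replicate number 2. Of 16 tested members 6 passed limma as higher and 0 as lower (Fisher's exact test against other genes, two-sided, adjusted p = 3.25e-06 over 24 lists), while ATF4, ATF5 and SLC7A5 were not higher on both arrays of number 2. For the list as a whole camera gave adjusted p = 2.98e-08, and 0.546 with an estimated correlation. CHAC1, which degrades glutathione, differed by 2.01 ± 0.33 (SE, adjusted p = 0.0121), DDIT4, an inhibitor of mTORC1 signalling, by 1.59 ± 0.13 (0.000312), and ASNS, the asparagine synthetase, by 0.82 ± 0.12 (0.011). DDIT4 read 1767 and 4610 in untreated replicates 1 and 2 and 1565 and 5427 in LPA replicates 1 and 2. Of 14 hypoxia response genes 5 were called higher and 0 lower (Fisher's adjusted p = 2.55e-05; camera 3.2e-08, and 0.728 with an estimated correlation), among them ANKRD37 (1.69 ± 0.18), VEGFA, the endothelial growth factor (0.72 ± 0.14), and PDK1, which limits pyruvate entry into mitochondria (0.60 ± 0.14).

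FOXO and starvation targets had 4 of 16 members called higher in number 2 (Fisher's adjusted p = 0.000918), while camera did not pass the list (adjusted p = 0.127, and 0.728 with an estimated correlation). The 4 were TXNIP and ARRDC4, arrestin-like genes that respond to glucose (1.57 ± 0.24 and 0.85 ± 0.17), CITED2 (1.04 ± 0.21) and SESN1 (0.74 ± 0.15). Ribosome biogenesis genes had a mean of -0.25 in number 2 against number 1, where camera gave adjusted p = 0.0297 and 0.728 with an estimated correlation, and cholesterol synthesis genes a mean of 0.22 (0.0412, and 0.728 with an estimated correlation). Under quantile normalization 514 genes were called between numbers, 420 of them shared with the 445, and under median centring 364 (81 higher, 283 lower), of which 319 were shared. The count of higher members was 6 in the integrated stress response under both, while under median centring it was 4 for hypoxia and 3 for FOXO targets. These genes were chosen after their values were seen.

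Immediate early genes differed less between LPA and untreated cells in replicate number 2 than in number 1, and that difference was not tested. A hypothesis was that they may already have been high in untreated replicate 2. Their median was 0.16 higher there than in untreated replicate 1, at percentile 95.7 of lists matched on brightness. That is short of the limit set beforehand (a median of 0.187), but by less than the SE over members (0.143), a margin brought in after the result was seen, so the test decides neither way and the hypothesis stays open. Between numbers limma called EGR1 higher in number 2 (1.14 ± 0.20, adjusted p = 0.0156) and KLF6 lower (-0.50 ± 0.12, 0.0431).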
